A study of Drosophila melanogaster with 63 samples.

How the data were processed

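Total RNA of Drosophila melanogaster embryos was measured on 2-colour arrays, with the sample in Cy3 and a common reference collected over 0 to 22 h of embryogenesis in Cy5 on all 63 arrays, per the labels. Per the labels' protocols, RNA was extracted with Trizol, the mutants were kept over GFP balancer chromosomes, and embryos of the wanted stages were collected and genotyped. The authors deposited a single table of log ratios, 1 column per array. Per the submitters' processing notes limma was used, with no version given; background correction, within-array normalization and filters are not given in the sources used here. The deposited values were taken as log2 ratios, the scale on which limma gives log ratios, although neither the base nor the side of the reference is stated. All arrays held the same set of sorted values to within 0.000784, so the deposited log2 values had already been quantile normalized between arrays, which the plan had not foreseen, and each array had a median of 0.00509. Values ran from -3.74 to 2.78. Of 20000 deposited rows, 6772 were blank on every array, and the other 13228 had a value on every array.

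The direction of the ratio was set by a rule written before the data were examined. In wild type the maternal list had a median of -0.438 at 2 h and -0.937 at 10 h, the cellularization list 0.959 and -0.819, and the muscle list -1.62 and -1.50. These lists all moved as sample over reference requires, so values were used as deposited; the direction is likely and rests on these lists, of which the muscle list moved by little. No pair of arrays correlated clearly below 0 (lowest r = -0.0336).

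Rows were named through the platform annotation, updated by gene ID for 10093 rows. There were 10096 rows with 1 gene symbol, 220 with several and 2912 without a name here. Rows of 1 symbol were averaged per array, which concerned 696 genes with more than 1 row and gave 9292 named genes and 3132 other features, 12424 in all. Genes whose rows disagreed in sign are marked where they are called.

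The labels put the 63 arrays into 21 groups of 3, by genotype and hours after egg laying. All arrays entered 1 linear model in limma 3.58.1 (R 4.3.3, statmod 1.5.0) with a mean for each group and 42 residual degrees of freedom, followed by empirical Bayes moderation. Each mutant was contrasted with wild type, and the mutants with each other, over the mean of 6, 7, 8, 9 and 10 h (15 arrays per genotype), and each mutant with wild type at 2 h and at 3 h. Further tests were F tests of the wild type time course and of whether a mutant's difference from wild type changed over 6 to 10 h, and 3 steps of the wild type time course. Tests were 2-sided, with Benjamini-Hochberg adjustment within a contrast and a threshold of 0.05. A feature that passed is described as called. In results of 3 arrays against 3 the adjusted p comes from this limma model, which pools the spread over all groups.

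Lists of genes, 27 in number, were written before the data were examined and tested with camera for 10 contrasts, with a preset correlation of 0.01 and again with an estimated one, and with fry. Named genes followed a rule also fixed beforehand. For the mean contrasts it took eve, ftz and the 10 largest differences in each direction among named genes that passed and kept their sign at all 5 times. For the contrasts at 2 h, at 3 h and between wild type times it took the 5 largest in each direction whose 3 replicates of a group all lay above the 3 of the other. From the lists it took up to 4 members past the threshold, and the segment polarity and pair-rule members whatever their p.

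The age of each array at 6 to 10 h was the point on the linearly interpolated wild type mean profile with the highest Pearson correlation, a wild type array being set against the other wild type arrays, and genotypes were compared with a permutation test of labels within time (100000 resamples). Runs of slide numbers, taken from the numbers in the sample titles, were used as possible batches. Some slide numbers occur more than once, so a run may join arrays of unlike batches. A test of whether called genes gather on chromosome 2 or chromosome 3 was void, since 77.1% and 76.1% of the called sets had a known place and 80% had been required.

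The model was tested on simulated data with the real wild type means at each time and the real spread of each feature, 12424 features and 200 changed ones. For the eve contrast over 6 to 10 h it recovered 68% of changes of 0.25 log2 units, 96% of 0.5 and 100% of 1, with 10 unchanged features called. For eve at 2 h it recovered 12%, 48% and 98%, with 7 unchanged features called, and for eve at 3 h 8%, 52% and 92%, with 8. With no changed feature in ftz, 1 of 12424 was called over 6 to 10 h. In simulated eve arrays with the age of their label the estimated offset was -0.0633 h over 6 to 10 h, and in arrays 1 h older than labelled it was 0.693 h. Alternatives covered scaling, filtering, the handling of rows, the samples in the model, array weights, blocks, age and left-out arrays. The number of arrays limits the precision, and no background signals were used here.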

Results

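Gene expression was measured in Drosophila melanogaster embryos of 3 genotypes over a developmental time course: wild type, mutants for even skipped (eve) and mutants for fushi tarazu (ftz). Both genes encode homeodomain proteins of the pair-rule class, which divide the early embryo into segments. Embryos were taken at 2, 3, 6, 7, 8, 9 and 10 h after egg laying, with 3 arrays for each genotype and time and 63 arrays in all. Each array set the RNA of a sample against a common reference collected over 0 to 22 h of embryogenesis, and a value is the log2 ratio of sample to reference on that array. The arrays carried 13228 rows with values, which gave 12424 features, 9292 of them named genes. Replicate arrays of a group correlated with r between 0.514 and 0.953 over features (median 0.826). Nothing in the labels says that replicates came from separate collections, so p-values measure the spread between these arrays, and the number of arrays limits the precision.

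The targeted genes were examined in every group before the comparisons. The eve transcript stood at -1.20 ± 0.14 (SD, n = 3) in eve mutants at 2 h and at 0.51 ± 0.18 (SD, n = 3) in wild type, a difference of -1.71 log2 units (SE 0.16; limma, Benjamini-Hochberg adjusted p = 3.11e-11). It was also lower in eve mutants over 6 to 10 h, by -0.50 (SE 0.07, n = 15 arrays per genotype). At 3 h it was not lower: the difference was 0.21 (SE 0.16; limma, Benjamini-Hochberg adjusted p = 0.499), so the eve label of the 3 h arrays is not borne out by this transcript. The ftz transcript in ftz mutants lay close to wild type, at 0.67 ± 0.12 (SD, n = 3) against 0.82 ± 0.03 (SD, n = 3) at 2 h, and over 6 to 10 h the difference was 0.03 (SE 0.07). The alleles are not named in the labels and a mutant allele can still be transcribed, so the ftz transcript neither bears out nor contradicts the ftz label. In eve mutants at 2 h the ftz transcript was lower than in wild type by -1.14 (SE 0.15; limma, Benjamini-Hochberg adjusted p = 1.53e-07), and in ftz mutants at 2 h the eve transcript was lower by -0.67 (SE 0.16; adjusted p = 0.00603).

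**Figure D1:**
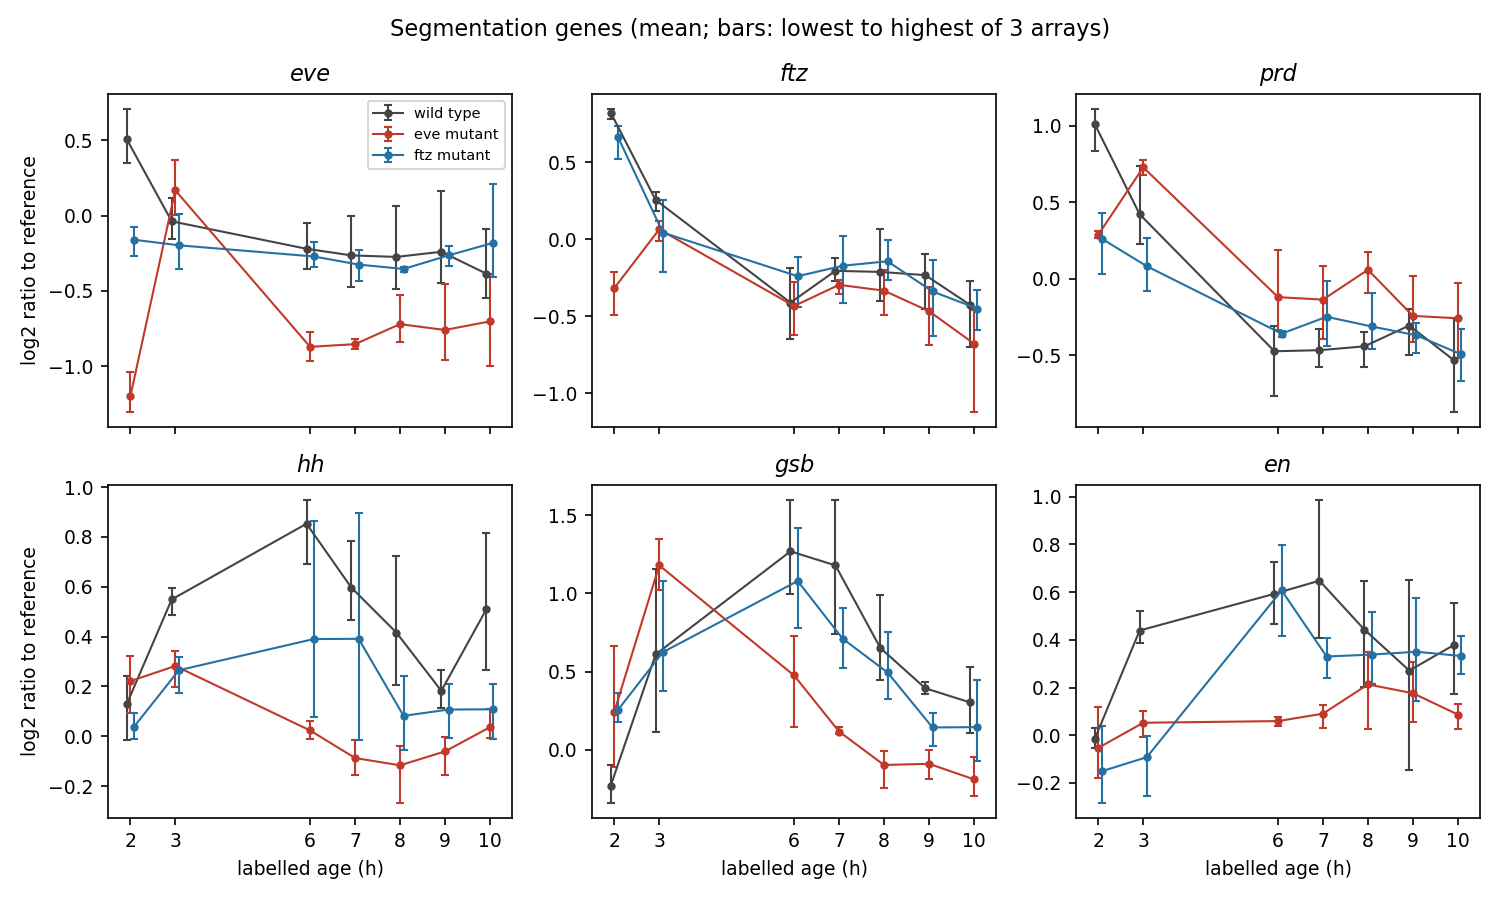
Log2 ratio to the common reference of 6 segmentation genes against the labelled age in hours, for wild type, eve mutants and ftz mutants; points are means and bars run from the lowest to the highest of 3 arrays. At 2 h the eve transcript was at 0.51 in wild type and at -1.20 in eve mutants, and over 6 to 10 h hh and gsb were lowest in eve mutants at every time.

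The comparison of eve mutants with wild type over 6 to 10 h asks what expression looked like in these mutants, hours after eve acts early in segmentation. The design does not separate a mutation from the background of the stock that carried it. Of the segment polarity genes, which hold the borders within each segment, several were lower in eve mutants, but the list did not pass camera with an estimated correlation. Of 10 measured members 5 were lower and none was higher, and 6 were lower when adjusted over the list alone. The paired-domain gene gsb was lower by -0.72 log2 units (SE 0.09), the signalling gene hh by -0.55 (SE 0.07), the engrailed paralog inv by -0.38 (SE 0.06). Lower too were en itself by -0.34 (SE 0.06) and the receptor gene smo by -0.25 (SE 0.08), over 15 arrays per genotype. Values that did not pass the test were 0.12 for mid (SE 0.10), 0.11 for ci (SE 0.16), -0.10 for nkd (SE 0.06), -0.10 for gsb-n (SE 0.08) and -0.09 for H15 (SE 0.04). The list as a whole lay lower than other genes (camera in limma, Benjamini-Hochberg adjusted p = 0.0139; adjusted p = 0.126 with an estimated correlation). With the estimated age of each array as a covariate gsb, hh, inv and en were lower, smo did not pass, and ci was higher by 0.92. The wild type arrays varied widely in ci, for example from 0.324 to 2.06 at 6 h.

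Among 9 measured pair-rule genes, eve, slp2 (-0.34, SE 0.09) and sob (-0.24, SE 0.07) were lower, while prd (0.30, SE 0.07) and hry, the hairy gene (0.37, SE 0.05), were higher. With the age covariate slp2 (-0.03), sob (-0.14) and prd (0.25) no longer passed. The gap gene Kr was lower by -0.70 (SE 0.09) and hb by -0.29 (SE 0.08). In the early mesoderm and heart list 7 of 10 genes were lower, among them bap (-0.45, SE 0.05), the FGF receptor gene htl (-0.39, SE 0.06) and sna (-0.44, SE 0.07), and 1, lmd, was higher by 0.35 (SE 0.10), with the same counts adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0207; adjusted p = 0.171 with an estimated correlation). DNA replication and cell cycle genes were lower in 11 of 12 cases, and in 11 adjusted over the list alone, with fzy, the Cdc20 activator of the anaphase-promoting complex, at -1.18 (SE 0.08), Mcm5 at -0.84 (SE 0.08) and PCNA at -0.62 (SE 0.08) (camera, Benjamini-Hochberg adjusted p = 2.05e-07; adjusted p = 0.0958 with an estimated correlation). The same list fell in wild type between 6 and 10 h, and the eve arrays resembled wild type arrays that were on average 1.03 h older. Ribosomal protein genes were lower in 7 of 10 cases, with RpS18 at -0.99 (SE 0.13) and RpL32 at -0.79 (SE 0.12), and 1 was higher, with the same counts adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0147; adjusted p = 0.472 with an estimated correlation). Muscle genes did not pass as a list (camera, adjusted p = 0.0631), although 8 of 11 were higher singly, among them bt (0.74, SE 0.18) and TpnC73F (0.58, SE 0.10). Another 2 were lower, among them Mlp84B, a muscle LIM protein gene, by -1.25 (SE 0.17). With the age covariate 2 mesoderm genes were called lower at a list median of -0.232 after -0.237, and 2 muscle genes higher and 2 lower at 0.421 after 0.364. There 4 DNA replication genes were lower at -0.209 after -0.427, and 1 ribosomal protein gene was lower and 1 higher at -0.0771 after -0.346. The median SE over called features went from 0.0643 to 0.11.

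Among genes with 1 direction at all 5 times, the largest differences apart from fzy lay outside these lists. The peroxiredoxin gene Prx6c was 4.32-fold higher in eve mutants, at 2.25 ± 0.30 (SD, n = 15) against 0.14 ± 0.28 (SD, n = 15) in wild type. These SDs are of arrays within a time, pooled over the 5 times, and leave out the spread between times. The neuropeptide precursor gene Orcokinin was 3.16-fold higher, the cuticle protein gene Ccp84Ad 2.92-fold and CG5171 2.86-fold. Also higher were Neurochondrin 2.64-fold, the cytochrome P450 gene Cyp6a8 2.56-fold, CG7966 2.34-fold, CG4306 and the Arp2/3 complex subunit gene Arpc1 2.14-fold, and the ornithine aminotransferase gene Oat 2.06-fold. The maltase genes Mal-A3 and Mal-A1 were 2.88-fold and 2.52-fold lower, sala 2.68-fold, Acp62F 2.56-fold. Lower as well were CG6282 2.36-fold, the betaine-homocysteine methyltransferase gene Bhmt 2.22-fold, the insulin-binding protein gene ImpL2 2.21-fold, the ion transport peptide gene ITP 2.08-fold and the vitamin transporter gene Smvt 2.02-fold. Each of these genes, and fzy, differed in 1 direction at all 5 times, and limma's Benjamini-Hochberg adjusted p was at most 1.9e-06 for each. With the estimated age as a covariate Neurochondrin, CG4306, Oat and Smvt no longer passed.

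By limma with Benjamini-Hochberg adjustment, 4901 of 12424 features differed between eve mutants and wild type over 6 to 10 h, 2439 higher and 2462 lower. Most differences were small: the median size was 0.25 log2 units, and 307 features differed by at least 1.5-fold. With the estimated age of each array as a covariate 1283 features were called, and with the 5 times averaged into 3 values per genotype 2191. Within the slide run that held 17 of these arrays 99.9% of the called features kept their sign, and 90.7% did between the 2 arrays of a second run that shared a time; these arrays also entered the main estimate.

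The comparison of ftz mutants with wild type over 6 to 10 h asks the same of the other gene. DNA replication and cell cycle genes were again lower in 11 of 12 cases, and in 11 adjusted over the list alone, with fzy at -1.02 log2 units (SE 0.08), Mcm5 at -0.86 (SE 0.08), CycB at -0.58 (SE 0.13) and CycE at -0.55 (SE 0.07) (camera in limma, Benjamini-Hochberg adjusted p = 5.34e-08; adjusted p = 0.0689 with an estimated correlation). The ftz arrays resembled wild type arrays that were on average 1.24 h older, and with the estimated age as a covariate 1 of the 12 was lower. No other list passed camera. Of 10 segment polarity genes 5 were lower and 2 higher, and 6 and 2 adjusted over the list alone (adjusted p = 0.478): hh was lower by -0.30 (SE 0.07), inv by -0.28 (SE 0.06), smo by -0.27 (SE 0.08), gsb by -0.25 (SE 0.09) and H15 by -0.12 (SE 0.04, with its array rows of opposite sign), and gsb-n (0.28, SE 0.08) and mid (0.26, SE 0.10) were higher. With runs of slide numbers as a term none of these 7 passed, at -0.34 for gsb, 0.27 for gsb-n, -0.18 for inv, -0.15 for smo, 0.14 for mid, -0.09 for hh and -0.05 for H15, as the median SE over called features went from 0.0651 to 0.1. With the estimated age as a covariate inv was lower and gsb-n higher, and ci was higher by 0.91, while gsb (-0.00602), hh (-0.13), smo (0.00289), mid (0.03) and H15 (-0.10) did not pass. For en, nkd and ci the values of -0.08 (SE 0.06), -0.14 (SE 0.06) and -0.06 (SE 0.16) did not pass.

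Among the pair-rule genes hry was higher by 0.17 (SE 0.05) and Ten-m lower by -0.14 (SE 0.06), and the other 7 did not pass. With slide runs as a term Ten-m stood at 0.0163 and did not pass, and with the age covariate neither gene did, at 0.13 for hry and -0.10 for Ten-m. Of the gap genes Kr was lower by -0.52 (SE 0.09), hb by -0.39 (SE 0.08), cnc by -0.31 (SE 0.08) and hkb by -0.26 (SE 0.05). The muscle list did not pass (adjusted p = 0.071), with 8 of 11 genes higher, among them TpnC73F (0.97, SE 0.10) and the myosin light chain genes Mlc2 (0.87, SE 0.14) and Mlc1 (0.55, SE 0.13), and Mlp84B lower by -0.61 (SE 0.17), while 4 muscle genes were higher with the age covariate and 3 with slide runs as a term. The myoblast gene lmd was higher by 0.84 (SE 0.10) and sna lower by -0.42 (SE 0.07). The tracheal chitin-binding genes serp and verm were higher by 0.69 (SE 0.10) and 0.64 (SE 0.08, with the array rows of verm of opposite sign).

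The translation initiation factor gene eIF4E3 showed the largest difference, 4.76-fold higher in ftz mutants. It stood at 2.41 ± 0.40 (SD, n = 15) against 0.16 ± 0.30 (SD, n = 15) in wild type, with SDs again pooled within the 5 times. Prx6c was 3.71-fold higher, CG9184 3.24-fold, Oat 2.95-fold, CG13159 and CG7675 2.51-fold, CG9628 and CG5171 2.40-fold. Higher too were the lamin B receptor gene LBR 2.37-fold and the cuticle protein gene TwdlM 2.36-fold. ITP was 2.63-fold lower, the cathepsin gene cathD and the amino acid transporter gene path 2.46-fold, Acp62F 2.44-fold. Smaller decreases were seen for CG9799 2.17-fold, Cyp6v1 2.13-fold, akirin 2.08-fold, fzy 2.03-fold, CG4408 1.99-fold and Smvt 1.97-fold. Each of the 20 kept its direction at all 5 times, with limma's Benjamini-Hochberg adjusted p of at most 1.78e-06. With the estimated age as a covariate Oat, CG7675, Cyp6v1, akirin, CG4408 and Smvt no longer passed.

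In all, 5023 features differed between ftz mutants and wild type over 6 to 10 h (limma, Benjamini-Hochberg), 2573 higher and 2450 lower, with a median size of 0.26 log2 units and 362 of at least 1.5-fold. The count was 2122 with runs of slide numbers as a term, 1243 with the estimated age as a covariate and 2354 with the 5 times averaged into 3 values per genotype. Within the only slide run that held both genotypes at a shared time, in 5 arrays at 2 times, 94.5% of the called features kept their sign; these arrays also entered the main estimate.

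The mutants were compared with each other to see where they differed. Several mesoderm and trachea genes were lower in eve than in ftz mutants, and several early embryonic transcripts were higher. None of the lists below passed camera with an estimated correlation. The slide run that both mutants shared at 6 to 10 h held 3 eve and 6 ftz arrays, so a run effect on these lists was hardly separable. In the early mesoderm and heart list 5 of 10 genes were lower and none higher, with lmd at -0.49 (SE 0.10), htl at -0.39 (SE 0.06), Him at -0.38 (SE 0.08) and eya at -0.32 (SE 0.06), and 5 were lower adjusted over the list alone (camera in limma, Benjamini-Hochberg adjusted p = 0.0196; adjusted p = 0.208 with an estimated correlation). In the trachea list 6 of 8 were lower, with serp at -0.71 (SE 0.10) and verm at -0.47 (SE 0.08), and pyd was higher by 0.29 (SE 0.09), with the same counts adjusted over the list alone (adjusted p = 0.0259; adjusted p = 0.258 with an estimated correlation). Mitochondrial energy genes were lower in 6 of 11 cases, among them ATPsynC (-0.72, SE 0.10) and COX5A (-0.56, SE 0.08), and 1 was higher, while 7 were lower adjusted over the list alone (adjusted p = 0.0152; adjusted p = 0.208 with an estimated correlation). Maternal transcripts were higher in 7 of 16 cases, with the germline RNA helicase gene spn-E at 1.31 (SE 0.13) and tor at 0.59 (SE 0.11), and 1 was lower, while 8 were higher adjusted over the list alone (adjusted p = 0.0152; adjusted p = 0.258 with an estimated correlation). Cellularization genes were higher in 5 of 9 cases, with Sry-alpha at 1.15 (SE 0.16) and bnk at 0.54 (SE 0.09), none was lower, and 5 were higher adjusted over the list alone (adjusted p = 0.0259; adjusted p = 0.228 with an estimated correlation).

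Of the segmentation genes, eve (-0.50, SE 0.07), gsb (-0.47, SE 0.09), slp2 (-0.39, SE 0.09), gsb-n (-0.38, SE 0.08), en (-0.27, SE 0.06), hh (-0.26, SE 0.07), sob (-0.24, SE 0.07) and ftz (-0.17, SE 0.07) were lower in eve than in ftz mutants, and prd (0.22, SE 0.07) and hry (0.19, SE 0.05) were higher. With slide runs as a term eve (-0.24), en (-0.21), sob (-0.16), ftz (-0.27), prd (0.18) and hry (0.05) no longer passed. The segment polarity list itself did not pass (camera, adjusted p = 0.182). Orcokinin was 3.05-fold higher in eve mutants, Marf1 2.82-fold, spn-E 2.48-fold, CG14569 2.29-fold, CG15047 2.27-fold and Sry-alpha 2.22-fold. CG6282 was 2.94-fold lower, eIF4E3 2.67-fold, CG9184 2.50-fold, LBR 2.36-fold. Smaller differences were found for CG13159 2.23-fold, CG10154 2.14-fold, the gluconeogenic enzyme gene Pepck2 2.02-fold and the glutathione transferase gene Mgstl 1.92-fold. Of the 20 largest, CG14915, EAChm and Mal-A1 no longer passed with runs of slide numbers as a term. The test called 4477 features, 2155 higher and 2322 lower (limma, Benjamini-Hochberg), with 233 of at least 1.5-fold. The count was 1741 with runs of slide numbers as a term and 1598 with the 5 times averaged. In a run that held both mutants at 3 shared times, in 6 arrays, 81.4% of the called features kept their sign; these arrays also entered the main estimate.

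Many features moved the same way in both mutants. Of the calls against wild type, 1233 were higher in both and 1269 lower in both, where independent lists would share 505.1 and 485.5, and 131 were called in opposite directions, where 990.8 would be. Both comparisons used the same wild type arrays, which raises such agreement. Over features the differences of eve and ftz from wild type correlated with r = 0.596, and simulated mutants with no effect gave 0.498 from the shared arrays alone. The covariance was 0.0327 against a simulated 0.00259, a difference of 0.0301. With the wild type arrays split between the comparisons the correlation had a median of 0.497 over 50 splits (0.289 to 0.582) and the covariance a median of 0.0292. Prx6c, Oat and CG5171 were among the 10 largest increases in both comparisons, and Acp62F, fzy, ITP and Smvt among the 10 largest decreases. Both mutants also looked older than wild type, by 1.03 h and 1.24 h, which a split of the wild type arrays does not remove. With the estimated age as a covariate Oat and Smvt no longer passed in either comparison.

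At 2 h, when the pair-rule genes are active, eve mutants had lower levels of the pair-rule genes as a group. Of 9 measured members 7 were lower and none was higher: besides eve and ftz, prd was lower by -0.72 (SE 0.15), sob by -0.65 (SE 0.16), odd by -0.50 (SE 0.13), ftz-f1 by -0.45 (SE 0.10) and hry by -0.32 (SE 0.12), with 3 arrays per group, and 7 were lower adjusted over the list alone (camera in limma, Benjamini-Hochberg adjusted p = 0.000105; adjusted p = 0.0161 with an estimated correlation). In the same arrays 65.7% of the features that rose from 6 to 10 h in wild type were higher than in wild type, the cuticle list had a median of -0.0535 against -0.871, and replicate 2 correlated least with its group (mean r 0.667). Cell death genes were lower in 3 of 6 cases, with grim at -0.75 (SE 0.11), Corp at -0.60 (SE 0.18) and skl at -0.48 (SE 0.10), and in 5 adjusted over the list alone (adjusted p = 0.0081; adjusted p = 0.065 with an estimated correlation). Ribosomal protein genes were higher in 4 of 10 cases, with RpS18 at 1.83 (SE 0.29) and RpS12 at 1.29 (SE 0.23), and in 5 adjusted over the list alone (adjusted p = 0.000874; adjusted p = 0.297 with an estimated correlation). Besides RpS18, the largest increases were CG10591 (11.0-fold), the larval cuticle protein gene Lcp65Ag2 (4.40-fold), the polyubiquitin gene Ubi-p63E (4.21-fold) and CG15022 (3.70-fold). The ecdysteroid synthesis gene spo was 5.17-fold lower, the glutathione transferase gene GstT4 3.58-fold. Next came the cuticle protein gene TwdlK 3.30-fold, eve 3.26-fold and CG13377 3.21-fold. The count was 2682 features, 1281 higher and 1401 lower (limma, Benjamini-Hochberg), 1132 of them at least 1.5-fold.

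At 3 h genes of the cellularization list, which fell in wild type from 2 to 3 h, were higher in eve mutants. Of 9 members 4 were higher and none lower: bnk by 1.60 (SE 0.21), halo by 1.52 (SE 0.225), term by 1.15 (SE 0.35) and zen by 0.85 (SE 0.27), and 5 were higher adjusted over the list alone (camera in limma, Benjamini-Hochberg adjusted p = 1.73e-05; adjusted p = 0.00507 with an estimated correlation). Mitochondrial energy genes were higher in 2 of 11 cases, ATPsynbeta (0.83, SE 0.24) and porin (0.39, SE 0.11), and in 6 adjusted over the list alone (adjusted p = 0.0221; adjusted p = 0.27 with an estimated correlation). DNA replication genes were lower in 3 of 12 cases, and in 4 adjusted over the list alone (adjusted p = 0.0134; adjusted p = 0.38 with an estimated correlation). None of the segment polarity genes passed at 3 h, where 4 were lower and 1 higher adjusted over the list alone, and Ten-m was lower by -0.42 (SE 0.125). STUB1 was 4.14-fold higher, CG14915 4.02-fold, CG15876 3.96-fold and GstE11 3.09-fold. In contrast LBR was 3.35-fold lower, the gap junction gene Inx2 2.59-fold, beta-Spec 2.22-fold, the gluconeogenic enzyme gene Pepck1 2.17-fold and the microtubule-binding protein gene ens 2.16-fold. The count was 1189 features, 671 higher and 518 lower (limma, Benjamini-Hochberg). It was 638 without eve replicate 2, 634 without eve replicate 3 and 747 without wild type replicate 3. At 3 h the eve transcript did not bear out the label, and each genotype lay in a slide run of its own, so no value within a run exists, and with runs as a term 226 features were called.

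In ftz mutants at 2 h 4 of 9 pair-rule genes were lower and none higher: prd by -0.75 (SE 0.15), eve by -0.67 (SE 0.16), hry by -0.57 (SE 0.12) and odd by -0.45 (SE 0.13), and 4 were lower adjusted over the list alone (camera in limma, Benjamini-Hochberg adjusted p = 0.00216; adjusted p = 0.0765 with an estimated correlation). The gap genes Kr and hkb were lower by -0.64 (SE 0.20) and -0.52 (SE 0.12), the only calls among 9 of their list, where 3 were lower adjusted over the list alone (adjusted p = 0.00765; adjusted p = 0.19 with an estimated correlation). The Notch target E(spl)m7-HLH was higher by 0.70 (SE 0.19), the only call among 9, where 3 were higher adjusted over the list alone (adjusted p = 0.0492; adjusted p = 0.343 with an estimated correlation). Jon65Aiii, a serine protease gene, was 3.34-fold higher, the lysozyme gene LysE 3.09-fold, hoka 2.89-fold, CG17493 2.38-fold and Gtpx 2.34-fold. The nuclear pore gene Mgtor was 3.08-fold lower, Pepck1 2.81-fold, Ncc69 2.72-fold, the receptor gene Tl (Toll) 2.58-fold and Su(Tpl) 2.41-fold. The count was 758 features, 294 higher and 464 lower (limma, Benjamini-Hochberg). Of 1416 features called with only the groups compared 47.6% were higher, and of 2432 with array weights 45.7%. The count was 390 without ftz replicate 2 and 447 without wild type replicate 3.

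In ftz mutants at 3 h 10 lists passed camera, most with few members called singly, and none passed with an estimated correlation. The ftz and wild type arrays of 3 h lay in different slide runs, so a run effect was not separable. Segment polarity medians at 3 h were 0.459 in wild type, 0.0746 in eve and -0.0383 in ftz mutants. For EGFR signalling they were 0.263, 0.0533 and 0.00938, and for amnioserosa and dorsal ectoderm 0.405, 0.475 and 0.0184. The Hedgehog pathway transcription factor gene ci was lower by -1.56 (SE 0.35), en by -0.53 (SE 0.14) and nkd by -0.54 (SE 0.13), the only calls among 10 segment polarity genes and the count adjusted over the list alone being 3 as well (camera in limma, Benjamini-Hochberg adjusted p = 0.0367; adjusted p = 0.254 with an estimated correlation). In the pair-rule list hry was lower by -0.62 (SE 0.12) and Ten-m by -0.40 (SE 0.125), the 2 calls also adjusted over the list alone (adjusted p = 0.044; adjusted p = 0.254 with an estimated correlation). The Hedgehog pathway gene rdx was 3.37-fold lower, Parp1, the poly(ADP-ribose) polymerase gene, 4.02-fold, Cals 3.88-fold and the poly(A)-binding protein gene pAbp 3.22-fold. Amnioserosa and dorsal ectoderm genes were lower in 5 of 11 cases, with ush at -0.62 (SE 0.13) and tup at -0.56 (SE 0.13), and Doc1 was higher by 0.89 (SE 0.225), while 6 were lower adjusted over the list alone (adjusted p = 0.0367; adjusted p = 0.254 with an estimated correlation). Lower lists were also EGFR signalling, with 3 of 6 genes lower (adjusted p = 0.044; adjusted p = 0.254 with an estimated correlation), and JNK signalling, with 1 of 12 lower (adjusted p = 0.0367; adjusted p = 0.0838 with an estimated correlation). The gap list had 1 of 9 genes lower, the Hox and trunk selector list 2 of 4 and the trachea list 2 of 8 (each with adjusted p = 0.0472; adjusted p = 0.254 with an estimated correlation). Adjusted over the list alone, 3 EGFR, 1 JNK, 2 gap, 2 Hox and 2 trachea genes were lower. Mitochondrial energy genes were higher in 5 of 11 cases, with ATPsynbeta at 0.98 (SE 0.24) and blw at 0.77 (SE 0.22), and in 6 adjusted over the list alone (adjusted p = 0.00165; adjusted p = 0.0705 with an estimated correlation), and ribosomal protein genes in 3 of 10, with RpL32 at 0.89 (SE 0.28) and RpL15 at 0.77 (SE 0.21), and in 5 adjusted over the list alone (adjusted p = 0.0338; adjusted p = 0.334 with an estimated correlation). CG14111 was 2.82-fold higher, RpLP0 2.80-fold, RpL10Ab 2.79-fold, Rh50 2.63-fold and the ATP synthase subunit gene sun 2.58-fold. The count was 1704 features, 826 higher and 878 lower (limma, Benjamini-Hochberg). It was 1006 with slide runs as a term, 1077 without ftz replicate 1 and 1013 without ftz replicate 3.

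The time course in wild type gives the background of development against which the mutants were set. From 2 to 3 h the cellularization genes fell in 8 of 9 cases: term by -2.27 log2 units (SE 0.35), Sry-alpha by -2.09 (SE 0.35), bnk by -1.92 (SE 0.21) and halo by -1.87 (SE 0.225), and 8 fell adjusted over the list alone (camera in limma, Benjamini-Hochberg adjusted p = 1.48e-13; adjusted p = 2.55e-06 with an estimated correlation). Notch target genes rose in 6 of 9 cases, with E(spl)mdelta-HLH at 1.12 (SE 0.18) and E(spl)m7-HLH at 1.03 (SE 0.19), and in 8 adjusted over the list alone (adjusted p = 1.25e-07; adjusted p = 0.00995 with an estimated correlation). Maternal transcripts fell in 4 of 16 cases, among them plu (-1.41, SE 0.26) and the RNA regulator gene smg, and in 6 adjusted over the list alone (adjusted p = 0.00229; adjusted p = 0.117 with an estimated correlation). DNA replication genes rose in 4 of 12 cases, with Mcm3 at 0.98 (SE 0.15), and in 6 adjusted over the list alone (adjusted p = 0.00257; adjusted p = 0.209 with an estimated correlation). EGFR signalling genes rose in 3 of 6 cases and trachea genes in 1 of 8, and in 5 and 4 adjusted over the list alone (each with adjusted p = 0.00229; adjusted p = 0.0863 with an estimated correlation). The neural cadherin gene CadN rose 3.04-fold, ImpL2 3.17-fold and Prx6c 3.57-fold. Over the same hour CG14915 fell 7.78-fold, STUB1 6.13-fold, bard 5.75-fold, and the insulator protein genes Elba3 and Elba2 5.14-fold and 5.12-fold.

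From 3 to 6 h the Notch targets rose further in 3 of 9 cases, among them E(spl)m5-HLH by 0.79 (SE 0.17), and in 8 adjusted over the list alone (camera in limma, Benjamini-Hochberg adjusted p = 0.000338; adjusted p = 0.112 with an estimated correlation). Cellularization genes fell in 2 of 9 cases, bnk by -0.76 (SE 0.21) and zen2 by -0.51 (SE 0.10), and in 5 adjusted over the list alone (adjusted p = 0.00371; adjusted p = 0.112 with an estimated correlation). Smvt rose 4.96-fold and the kynurenine monooxygenase gene cn 3.33-fold, and Prx6c fell 3.42-fold. From 6 to 10 h DNA replication and cell cycle genes fell in 10 of 12 cases, with Mcm5 at -1.24 (SE 0.19), Mcm2 at -1.10 (SE 0.17) and PCNA at -1.03 (SE 0.19), and in 11 adjusted over the list alone (adjusted p = 8.07e-11; adjusted p = 0.0152 with an estimated correlation). The glutathione transferase gene GstE3 rose 7.95-fold, the lipophorin gene apolpp 6.91-fold and the cytochrome P450 gene Cyp4e2 6.12-fold, the pan-neuronal gene elav by 0.97 (SE 0.29) and the neural gene nerfin-1 by 1.46 (SE 0.17). Smvt fell 5.66-fold, the scavenger receptor gene Sr-CII 5.20-fold and CG15628 4.74-fold. The F test over the 7 times called 4802 features (limma, Benjamini-Hochberg). The single steps called 1516 features from 2 to 3 h, 900 from 3 to 6 h and 1567 from 6 to 10 h.

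**Figure D2:**
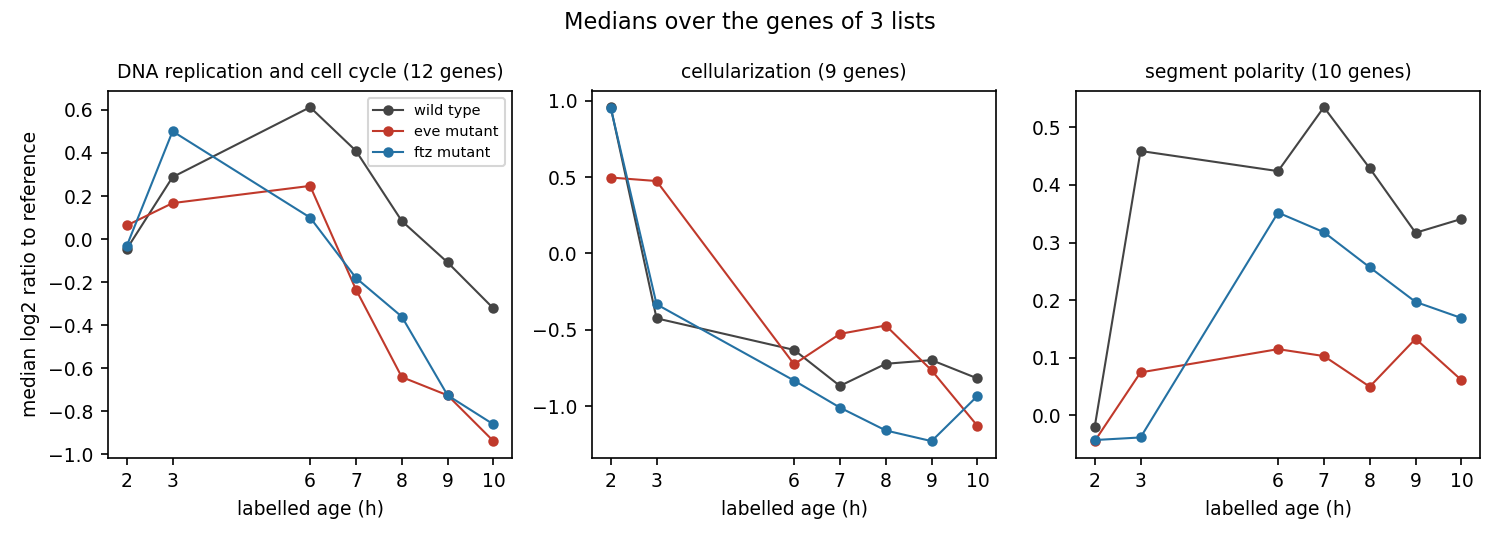
Median log2 ratio to the common reference over the measured genes of 3 lists against the labelled age in hours, with 1 line for each genotype. In wild type the 12 DNA replication and cell cycle genes had medians of 0.613 at 6 h and -0.323 at 10 h, and in eve mutants 0.247 at 6 h and -0.94 at 10 h.

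The developmental age of each array from 6 to 10 h was read from the wild type profile over the 1402 features that changed in wild type over these times. Arrays of eve mutants looked 0.98 ± 0.60 h (SD, n = 15) older than labelled and those of ftz mutants 1.19 ± 0.84 h (SD, n = 15) older, while wild type arrays lay at -0.05 ± 0.38 h (SD, n = 15). The difference from wild type was 1.03 h for eve and 1.24 h for ftz, each with a Benjamini-Hochberg adjusted p of 1.5e-05 in a 2-sided permutation test whose smallest possible p is 1e-05. The test exchanged single arrays within a time. Exchange of whole numbered series gives 10 splits, too few for a share under 0.05, and was not run for the age. Eve and ftz differed by -0.21 h (permutation p = 0.11). An age could not exceed 10 h, so offsets at the later times were limited, and the mean offset was 1.40 h in eve and 1.70 h in ftz at 6 h and -0.07 h and 0 h at 10 h.

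**Figure D3:**
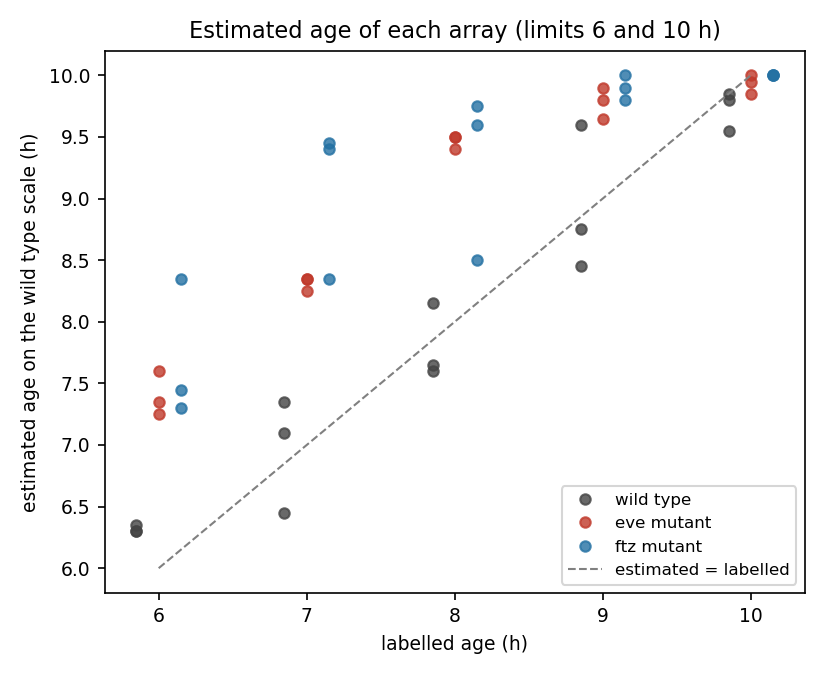
Estimated age in hours of each array on the wild type scale, which runs from 6 to 10 h, against its labelled age in hours, for 15 arrays per genotype; the dashed line marks equal ages. At 6, 7 and 8 h the mutant arrays lie above the wild type arrays of the same label.

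Differences from wild type were spread over the whole time course. At the single times from 6 to 10 h limma with Benjamini-Hochberg adjustment called 965, 1175, 675, 1081 and 992 features in eve mutants and 797, 1011, 950, 1009 and 1101 in ftz mutants. In eve mutants 23 features were higher and 41 lower at each of these 5 times, and in ftz mutants 33 and 37. At all 7 times eve mutants had 2 features higher, Arpc1 and the isocitrate dehydrogenase gene Idh3b, and 5 lower, of which Osi12 and ImpL2 have a gene name here. In ftz mutants 1 was higher at all 7 times, the mitochondrial ribosomal protein gene mRpL37, and 3 were lower, of which CG9799 and CG4511 are named. Idh3b, Osi12, mRpL37 and CG4511 were chosen after their values were seen.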

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

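The explanations for the cuticle genes at 2 h and the cellularization genes at 3 h, the slide run term, the comparisons with wild type 1 h and 2 h later, the splits of whole numbered series and the spread without 1 array were chosen only after results had been seen.

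Named genes whose difference from wild type over 6 to 10 h was not equal in the 2 mutants drew attention, by the limma test of eve against ftz mutants with Benjamini-Hochberg adjustment, and 27 of 35 passed. Orcokinin was 1.61 log2 units higher in eve than in ftz mutants, CG9799 1.03, Ccp84Ad 0.86, akirin 0.79, CG7966 0.77, Neurochondrin 0.53, Cyp6v1 0.53, Arpc1 0.52, Cyp6a8 0.42, path 0.38 and cathD 0.34. Lower in eve than in ftz mutants were ftz at -0.17, Bhmt at -0.48, ImpL2 at -0.49, eve at -0.50, Oat at -0.52, TwdlM at -0.65, CG7675 at -0.73, Mal-A3 at -0.78, CG9628 at -0.86 and sala at -0.91. Further ones were Mal-A1 at -0.9998, CG13159 at -1.16, LBR at -1.24, CG9184 at -1.32, eIF4E3 at -1.42 and CG6282 at -1.56. The sign against wild type was opposite in the mutants for 2 of the 27, CG6282 (-1.24 in eve, 0.315 in ftz) and ftz (-0.144 and 0.0288). With slide runs as a term 11 of the 27 no longer passed: Ccp84Ad (0.54), Cyp6v1 (0.55), path (0.15), ftz (-0.27), Bhmt (-0.26), ImpL2 (-0.29), eve (-0.24), Oat (-0.28), CG7675 (-0.36), Mal-A3 (-0.36) and Mal-A1 (-0.69). Over all features 4477 differed between the mutants. The difference from wild type changed over 6 to 10 h for 177 features in eve and for 134 in ftz mutants.

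Other splits of the arrays were counted for each comparison. For these counts the real split was the only 1 of 100 with as many calls: over 6 to 10 h 4901 for eve against wild type (highest other 1845), 5023 for ftz against wild type (1649), 4477 for eve against ftz (126), and over all 7 times 4802 for the wild type time course (2628), so chance can be excluded for these counts where single arrays are exchanged. Moving whole numbered series between genotypes gives 10 splits, too few for a share under 0.05, with 1129, 1000 and 421 as the highest others of the 3 genotype comparisons. At 2 and 3 h the 10 splits of 6 arrays are too few for a share under 0.05: the real counts and the highest others were 2682 and 152 for eve at 2 h, 1189 and 3 for eve at 3 h, 758 and 5 for ftz at 2 h, and 1704 and 10 for ftz at 3 h, each with 1 of 10 as large.

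Both mutants differed from wild type in 4901 and 5023 features at 6 to 10 h and looked about 1 h older. With the estimated age as a covariate the called features kept a median of 0.787 of their difference in eve mutants (0.766 to 0.809 without 1 array). That range lay above the bound of 0.75. In ftz mutants they kept 0.832 (0.729 to 0.845), a range across the bound that leaves this test undecided. The age slope came only from differences between replicates of a group, and the ratio was not tried on a simulated age shift. So the value in eve mutants does not decide whether age was the whole cause either. Set against wild type 1 h and 2 h later, the differences kept medians of 0.914 (0.894 to 0.929) and 0.827 (0.789 to 0.839) in eve and of 0.918 (0.901 to 0.93) and 0.819 (0.799 to 0.857) in ftz mutants, which argues against an equal shift of 1 h or 2 h as the whole cause in either. The calls fell to 1283 and 1243 as the median SE rose from 0.0643 to 0.11 and from 0.0651 to 0.127, and a part due to age may remain, since the age came from the same arrays and was capped at 10 h. With slide runs as a term the ratios were 1.03 in eve and 0.903 in ftz mutants. In eve mutants this argues against these runs as the whole cause, though some slide numbers occur more than once, so a run may join unlike batches. In ftz mutants the ratio was above 0.75 too but does not decide, since runs and genotype hardly overlapped. Of the ftz arrays of 6 to 10 h, 9 lay in a run with 2 such wild type arrays and 6 in a run with none. The median SE there rose from 0.0651 to 0.1. Genotype remains open as a hypothesis, beside an unequal age shift in either mutant and slide runs in ftz mutants. Genotype here includes the background of each stock, which the design does not separate from the mutation, and the chromosome test was void.

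Cuticle protein gene Lcp65Ag2 was among the largest increases in eve mutants at 2 h, while another cuticle protein gene, TwdlK, was among the largest decreases. Older embryos among those collected could bring transcripts of late genes: of 824 features that rose from 6 to 10 h in wild type, 65.7% were higher in eve mutants at 2 h (63 to 70.3% without 1 array), against 44.3% of the falling ones and 49.7% of all. The bound set beforehand was 65%, and the range spans it, so older embryos and a direct effect of eve cannot be told apart here. In the same arrays the maternal list had a median of -0.167 against -0.438 in wild type, and the cellularization list 0.498 against 0.959. Younger embryos among those collected were not tested at 2 h and stay open as well. The lower ftz and pair-rule values of the same arrays stand under the same limits. The eve transcript at -1.20 lay below every wild type mean (lowest -0.385). No wild type array was younger than 2 h, however, so this does not set younger embryos aside.

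Cellularization genes were higher in eve mutants at 3 h, and a younger age of these embryos may account for it. Of 839 features that fell from 2 to 3 h in wild type, 69% were higher in eve than in ftz mutants at 3 h (66.3 to 70.9% without 1 array), against 38.1% of the rising ones and 49% of all. These values are consistent with younger embryos. Slower early development of the mutant and a younger collection predict the same values, and each genotype lay in its own slide run at 3 h, so a run effect was not separable. The eve transcript of these arrays was not below wild type, so a wrong label also stays open, untested. Arpc1, Idh3b, ImpL2 and Osi12 cannot bear on it, since they were picked for a call at all 7 times, 3 h included.

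The eve replicate 3 arrays of 8 to 10 h differed from the other eve arrays along the ftz slide run difference with a correlation of 0.124 over features.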

How the results depend on the processing

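The slide run term, the fit without the 2 arrays farthest from their group and the comparison with wild type 1 h later were chosen after seeing the data. The cause of the changes below was not tested.

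Of the values of named genes under all settings, 1284 lost the call, 85 gained it, and 14 changed sign while called in the main fit or in the setting. The other 21401 kept direction and call or were called in neither fit, where a change of sign was not counted. Of the counts, 251 stayed within 1.5 times and 34 did not. With only the groups compared, eve at 3 h gave 1907 calls, ftz at 2 h 1416 and the wild type time course 3154. Array weights gave 2571 for eve at 3 h and 2432 and 2802 for ftz at 2 and 3 h. Averages of the numbered series, 3 against 3, gave 2191 for eve, 2354 for ftz and 1598 for eve against ftz, and the age covariate 1283 and 1243. At least 1.5-fold differed 307, 362 and 233 over 6 to 10 h, 1132 and 488 for eve at 2 and 3 h, and 390 and 700 for ftz. Slide runs gave 2122 for ftz, 1741 for eve against ftz, 226 for eve at 3 h and 1006 for ftz at 3 h. At an adjusted p under 0.01, 1546 calls were shared in place of 2502. For lists, 4 and 1 passed in eve and ftz over 6 to 10 h, 0 and 0 with an estimated correlation, and 20 and 9 by fry.

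Without 1 replicate the counts ran from 4035 to 5000 for eve and 4259 to 5175 for ftz over 6 to 10 h, 3343 to 4563 for eve against ftz, 1998 to 2499 and 634 to 1037 for eve at 2 and 3 h, 390 to 559 and 1013 to 1373 for ftz, and 4271 to 5142 for the wild type time course. The lowest counts at 3 h include 638 and 747 for eve and 1077 for ftz, and at 2 h 447 for ftz. Where 2 arrays remain in a group, the model pools the spread over groups. Without the 2 far arrays eve at 3 h gave 1402 and ftz at 2 h 944.

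Among values called in the main fit or in the setting, 14 signs changed. With the age covariate they changed for oc (-0.0167), hrg (-0.0669) and RpL27 (0.0901) in eve, and for smo (0.00289), ci (0.91), moody (-0.20), pnr (0.00622), Ppn (-0.0496) and COX4 (0.0833) in ftz mutants. With slide runs they changed for Ten-m (0.0163) and moody (-0.0366) in ftz, ple (0.0246) in eve against ftz and Mcm3 (0.0927) in eve at 3 h, and without wild type replicate 1 for ci in ftz, whose values without 1 replicate ran from -0.29 to 0.34.

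As a replicate block, the numbered series within a genotype (correlation 0.117) gave 3647, 3678 and 3107 calls over 6 to 10 h, and title numbers shared by the genotypes gave 4378 for eve against ftz, 2328 and 1595 for eve at 2 and 3 h, and 508 and 2257 for ftz. For arrays sharing a number, the deviations from their group means correlated between -0.26 and 0.0709 at 2 and 3 h (18 pairs, 0 over 0.1). At 6 to 10 h these correlations ran from -0.257 to 0.111 (15 pairs, 1 over 0.1). So arrays of a number hardly deviated together, which does not show whether their samples were handled together. Centring and quantile normalization moved nothing, as the deposited values were already normalized.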

Other observations

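The look at the profiles of single genes and the lists under the age covariate were chosen only after results had been seen.

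Prx6c was higher at 3 h than at 2 and 6 h in wild type, and high from 6 to 10 h in the mutants. Between 3 and 6 h no time was sampled, and the wild type arrays at 3 h lay in another slide run than most at 2 and 6 h. In wild type it stood at -0.17 at 2 h, 1.67 at 3 h and -0.10 at 6 h, while from 6 to 10 h eve mutants held 1.76 to 2.52 and ftz mutants 1.77 to 2.36 (3 arrays each). Arpc1, an actin nucleation gene, was higher in eve mutants at every time, for example at 0.14 against -0.52 at 2 h and 0.64 against -0.78 at 10 h. ImpL2 was lower at every time, at -1.22 against -0.56 at 2 h and -0.60 against 1.21 at 7 h.

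Lists moved unequally when the estimated age was a covariate. The median difference of the segment polarity genes in eve mutants went from -0.177 to -0.144, with gsb, hh, inv and en lower as before. The gene ci, not called before and widely spread among wild type arrays, was higher. That of the DNA replication and cell cycle genes went from -0.427 to -0.209 in eve mutants, with 4 of 12 lower, and from -0.455 to -0.154 in ftz mutants, with 1 lower. Against wild type 1 h later the DNA replication medians were -0.229, with 6 lower, and -0.257, with 7 lower. The early mesoderm and heart list in eve mutants had a median of -0.232 after -0.237, but 2 genes were called lower in place of 7. The ribosomal protein list went from -0.346 to -0.0771, with 1 lower and 1 higher in place of 7 and 1. The muscle list in eve mutants went from 0.364 to 0.421, with 2 higher and 2 lower in place of 8 and 2.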
